A study of Homo sapiens with 17 samples.

How the data were processed

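Messenger RNA was sequenced from 17 libraries of the human embryonic stem cell lines H7, HES-1 and HES-2, with libraries made by a stranded, bead-captured mRNA kit, per the labels' protocols. The deposited file gives a signal per gene, the authors' normalized count, for 30773 Ensembl genes in each of the 17 libraries. The submitters' processing notes name FastQC, Salmon and DESeq2, and do not say what each was used for. The notes name the genome builds GRCh38 and mm10 and give neither tool versions nor the part that mm10 played. Per the file headers the columns hold normalized counts. The deposited values are not whole numbers, and only 45.7 to 61.2% of the low values of a library lie on a common step of 0.825 to 1.331, so whole reads could not be recovered and tests that need counts were not used. All 30773 gene identifiers were found in GENCODE 29, 30691 of them paired with a symbol, and positions are given on GRCh38 from that annotation.

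The normalized totals were 21664000 to 22813000 per conventional library, 22685000 to 23865000 per LN library and 27178000 to 29397000 per naive library. Divided by the step of each library, they correspond to about 18761000 to 28429000 reads. Transcripts of the mitochondrial genome took 4.04 to 6.64% of the signal, and the 50 most abundant genes of a library took 12.7 to 16.2%. Replicates of the same group differed with an SD of 0.504 to 0.602 in log2 over genes. The labels do not say whether replicates were separate cultures, so the p-values measure only the spread between these libraries. Intervals from read counting were not computed, because counts were not given.

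Genes with a value of at least 10 in at least 2 libraries were tested (20740 genes), after adding 1 and taking log2. The cultures were compared with limma 3.58.1 in R 4.3.3 (linear model with terms for line and culture over all 17 libraries, moderated variances with a mean trend and robust estimation). Each p was adjusted by the Benjamini-Hochberg method over the tested genes, with 0.05 as the threshold, and changes are log2 fold changes ± SE. Effects within a line, and differences of these effects between lines, came from a limma model with a mean for each of the 8 groups. The difference between the 3 lines in the LN effect was an F test. A fold change against values near 0 depends on the added 1 and is no bound. Windows of 10 Mb and the arms of chromosome 1 were summarized over protein-coding genes with a mean of at least 100 over all libraries, a limit that high naive values can meet. Group means are arithmetic means of normalized counts, and means over a culture include all of its lines.

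Altogether 29 gene lists with 621 entries (586 tested) were fixed before the data were examined, as were the design, the alternatives and the rule for named genes. They cover core pluripotency, naive, primed and formative markers; markers of primitive streak and mesendoderm, neuroectoderm, amnion and trophoblast, hypoblast and visceral endoderm, and fibroblasts; cholesterol synthesis, fatty acid synthesis, glycolysis, nuclear and mitochondrially encoded respiratory chain genes, and hypoxia; targets of FGF and ERK, Nodal and TGF-beta, WNT, BMP, YAP and p53; basement membrane and integrins, DNA methylation, imprinted genes, cell cycle, the unfolded protein and ATF4 response, heat shock, class I antigen presentation and replication histones. Each list was tested against the other genes with limma's camera, two-sided, with a preset correlation of 0.01, adjusted over the 29 lists of a comparison. The same test with an estimated correlation and limma's fry, which asks whether a list moves on balance in a direction without comparing it with other genes, were run beside it.

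Named genes are, per comparison, the 10 largest increases and the 10 largest decreases among genes past the threshold with a mean of at least 100 in the higher culture and the same direction in every line; from each list up to 2 members that rose most and up to 2 that fell most; and POU5F1, SOX2, NANOG, KLF17, DPPA3, OTX2, ZIC2 and COL1A1 whatever their values. For the difference between lines they are the 10 genes with the smallest F-test p. A gene outside this rule is said to have been chosen after its values were seen. Genes near-identical to another gene, such as TUBB, KHDC1L, LEFTY1 and LEFTY2, ALPG, histones and metallothioneins, and genes with an antisense partner have uncertain values, since the way reads were shared between copies or strands is not stated.

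Simulated reads were drawn from the mean of each line, the real depth and the spread within groups, with 200 genes changed. On them the LN against conventional test over 20297 genes called 62.7% of genes changed by 0.5 log2, 88.1% of those changed by 1 and 100% of those changed by 2. It called 10 of 20097 unchanged genes. The simulated change was the same in every line. Differences between lines in the LN effect, which the real test counts as error, were thus absent from it. The same test within H7, over 20351 genes, called 26.9%, 73.1% and 97.0%, and 15 of 20151 unchanged genes. A simulated list of 20 genes raised by 0.5 was called by camera, and 0 of 28 unchanged lists were. The simulated genes were drawn independently of each other, so this could not show false calls from lists with correlated members. Alternatives tried were other pseudocounts, filters and scalings, each library and each line left out, other forms of the model and, chosen after the data were seen, the test without the long arm of chromosome 1 and without the H7 LN libraries. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. No sample was left out of the main tests.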

Results

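The series set out to ask whether human embryonic stem cells kept on laminin-111 in a defined medium take on properties of the early post-implantation epiblast. Bulk mRNA sequencing covered 3 human embryonic stem cell lines, H7, HES-1 and HES-2, in 3 cultures, all at 5% O2. Conventional (primed) cells grew on growth-arrested mouse fibroblast feeders with 20% serum replacement and FGF2 at 10 ng/ml. LN cells grew without feeders on mouse laminin-111 at about 8 µg per cm2, with B27 and N2 supplements in place of serum replacement and FGF2 at 20 ng/ml. The comparison of these cultures therefore joins feeders, matrix, supplements and FGF2 dose. Naive cells of HES-1 and HES-2 were kept in an inhibitor medium that holds cells in a state like the pre-implantation epiblast. There were 6 conventional libraries (2 per line), 7 LN libraries (2 of H7, 3 of HES-1, 2 of HES-2) and 4 naive libraries (2 per line). Normalized totals ran from 21664000 to 29397000 per library.

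Naive cells stood far from both other cultures, and LN cells lay nearer to conventional than to naive cells. Over the 1000 most variable genes, the distance between the mean log2 profiles of LN and conventional cells was 69.5 in H7, 60.2 in HES-1 and 71.8 in HES-2. The distance from conventional to naive cells was 175.6 in HES-1 and 185.02 in HES-2, and that from LN to naive cells was 171.8 and 179.9. Over genes, log2 differences between LN and conventional libraries of H7 had an SD of 1.01 to 1.05. Between LN libraries of H7 and of HES-1, which share the culture but not the line, the SD was 0.91 to 0.99. Between LN libraries of H7 and of HES-2 it was 1.092 to 1.155. LN libraries of H7 thus lay nearer to LN libraries of HES-1, but not of HES-2, than to conventional libraries of H7. LN and conventional libraries differed with an SD of 0.75 to 0.85 in HES-1 and 0.84 to 1.01 in HES-2. The first principal component held 67.1% of the variance and set the naive libraries (scores 127.8 to 131.9) apart from the rest (−48.6 to −33.7). On it the LN libraries of HES-2 lay 10.4 apart (−37.03 for replicate 0 and −47.4 for replicate 1), and the libraries of every other group lay 0.1 to 4.1 apart. Along the second and the third components (8.23% and 6.63%), LN libraries scored above the conventional libraries of the same line in all 3 lines.

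**Figure D1:**
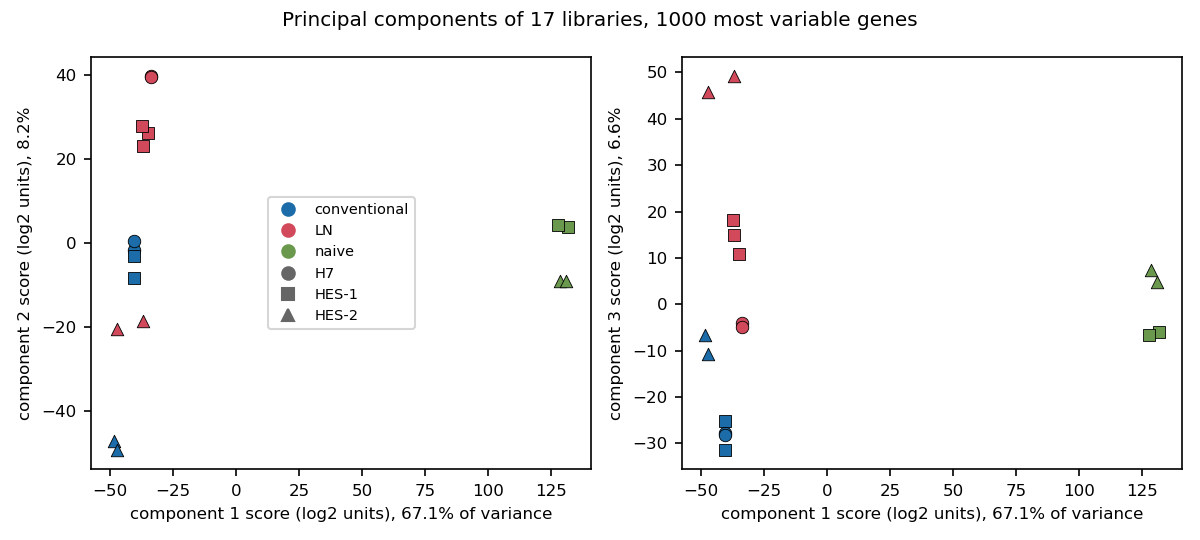
Scores of the 17 libraries on principal components 1, 2 and 3 of the 1000 most variable genes, in log2 units; colours stand for cultures and symbols for lines. Naive libraries lie at 127.8 to 131.9 on component 1 and the other libraries at −48.6 to −33.7.

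LN cells carried far less RNA of hypoblast, endoderm and primitive streak genes than conventional cells, and more RNA of lipid synthesis and mitotic genes. With an estimated correlation the hypoblast and fatty acid synthesis lists passed (adjusted p = 0.0367 for each), and streak (0.0838), cholesterol synthesis (0.250) and mitotic genes (0.135) did not. The Nodal antagonist CER1 fell from a mean of 8580 ± 5443 (SD, n = 6) to 67.1 ± 94.7 (SD, n = 7), a log2 change of −7.97 ± 0.75 (SE). POU5F1, the central pluripotency factor, had means of 11664 and 13258 (log2 change 0.16 ± 0.09, adjusted p = 0.226), and it passed only when HES-2 LN replicate 1 was left out (0.23, adjusted p = 0.0476). In all, 1823 genes were higher and 1893 lower in LN cells, of which 477 and 784 changed at least 2-fold.

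Hypoblast and visceral endoderm genes formed the list with the most negative median (−3.42). Of its 20 genes 17 fell, 0 rose and 3 did not pass, with 18 lower adjusted over the list alone (camera adjusted p = 2.04e-16, and adjusted p = 0.0367 with an estimated correlation). SOX17, a transcription factor of endoderm, fell from 497.8 to 8.30 (−6.41), and CER1, SOX17 and LEFTY2 each fell in all 3 lines. Of the 19 streak and mesendoderm genes 11 fell, 1 rose and 7 did not pass (median −2.40), with 13 lower adjusted over the list alone. Camera gave adjusted p = 1.24e-07 for them, and adjusted p = 0.0838 with an estimated correlation. The gene that rose was KDR, a VEGF receptor (1.55 ± 0.19). Among Nodal and TGF-beta ligands and targets 9 of 18 fell and 1 rose, also when adjusted over the list alone (median −0.62, adjusted p = 2.96e-05, and adjusted p = 0.204 with an estimated correlation). LEFTY2, a Nodal antagonist that Nodal itself induces, fell from a mean of 10349 to 383.6 (−6.45 ± 0.89), with the limit that it is near-identical to LEFTY1.

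WNT targets had 7 of 19 lower and 1 higher, and 8 lower and 1 higher adjusted over the list alone (median −0.71, adjusted p = 0.0199, and adjusted p = 0.204 with an estimated correlation). Among them LGR5, a receptor of R-spondins, fell by 5.05. BMP targets had 5 of 14 lower on both counts (median −0.75, adjusted p = 0.00612, and adjusted p = 0.445 with an estimated correlation), and the inhibitory SMAD6 fell by 2.35. The BMP median was −1.78 in H7, 0.08 in HES-1 and 0.11 in HES-2, so the list was lower by its median in H7 alone. YAP targets had 7 of 20 lower and 1 higher, and 10 and 3 adjusted over the list alone (median −0.43, adjusted p = 0.0124, and adjusted p = 0.3004 with an estimated correlation). ANKRD1, a classic YAP target, fell by 4.67. Without line H7 the calls of BMP (adjusted p = 0.784), YAP (adjusted p = 0.0607) and WNT targets (adjusted p = 0.0505) ended. The WNT call also ended without HES-1 (adjusted p = 0.0813) and with a filter at 50 (adjusted p = 0.0525).

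Other genes with large decreases were LINC02413 (−6.80), the glucose transporter gene SLC5A9 (−6.76), FGF17 (−6.72), the transcription factor gene FOXQ1 (−6.36) and NPPB (−6.36), which encodes a natriuretic peptide. CST1 (−6.32) and ERBB4 (−6.23), a neuregulin receptor, followed. Large increases were smaller in size: AADACL3 (3.58), PPP1R17 (3.01), D21S2088E (2.35), HMCN1 (2.34) and LHFPL6 (2.26). The zinc finger gene ZNF667 (2.83) and its antisense transcript ZNF667-AS1 (2.71) also rose, and a count without strand could not separate them.

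Lipid synthesis genes rose together. Of 26 cholesterol synthesis genes 21 rose, 0 fell and 5 did not pass (median 0.72), with 23 higher adjusted over the list alone. Camera gave adjusted p = 1.16e-10, and adjusted p = 0.250 with an estimated correlation. HMGCS1, an early enzyme of the mevalonate pathway, went from 4079 to 9744 (1.20 ± 0.22) and ACAT2 rose by 1.11 ± 0.16. Of 15 fatty acid synthesis genes 9 rose and 6 did not pass (median 0.60), with 12 higher adjusted over the list alone (adjusted p = 2.38e-08, and adjusted p = 0.0367 with an estimated correlation). SREBF1, a master regulator of lipogenic genes, rose by 1.16, and ACSS2, an acetyl-CoA synthetase, rose by 1.56. Genes of G2 and mitosis rose in 16 of 22 cases, 19 adjusted over the list alone (median 0.31, adjusted p = 2.03e-09, and adjusted p = 0.135 with an estimated correlation), among them CENPF (0.76), which encodes a kinetochore protein. Replication histones, whose RNA mostly lacks a poly(A) tail, were higher in 7 of 19 cases on both counts (median 0.56, adjusted p = 2.00e-05, and adjusted p = 0.204 with an estimated correlation), with H1-2 at 1.08.

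Some respiratory genes rose. Mitochondrially encoded genes rose in 9 of 13 cases on both counts (median 0.41, adjusted p = 2.43e-05, and adjusted p = 0.303 with an estimated correlation), with MT-CO2 at 0.51. Nuclear respiratory genes rose in 11 of 39, 14 adjusted over the list alone (median 0.13, adjusted p = 4.86e-04, and adjusted p = 0.328 with an estimated correlation), with SDHA at 0.36. Hypoxia genes fell in 8 of 20 cases and 0 rose, with 12 lower adjusted over the list alone (median −0.64, adjusted p = 8.71e-06, and adjusted p = 0.0838 with an estimated correlation). DDIT4 (−1.33) and BHLHE40 (−1.30) were among them. Glycolysis genes had 6 of 21 lower and 1 higher, and 7 and 1 adjusted over the list alone (median −0.15, adjusted p = 0.00319, and adjusted p = 0.331 with an estimated correlation). PFKFB3, whose product activates glycolysis, fell by 1.15. The glycolysis call ended without line H7 (adjusted p = 0.0505).

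Among p53 targets 8 of 19 rose and 1 fell, 10 and 1 adjusted over the list alone (median 0.23, adjusted p = 0.00319, and adjusted p = 0.3004 with an estimated correlation), and PHLDA3 rose by 1.30. Heat shock genes rose in 6 of 13, 7 adjusted over the list alone (median 0.20, adjusted p = 0.00733, and adjusted p = 0.328 with an estimated correlation). Unfolded protein and ATF4 genes fell in 10 of 22 cases, and 11 fell and 3 rose adjusted over the list alone (median −0.22, adjusted p = 0.0130, and adjusted p = 0.410 with an estimated correlation). The stress factors ATF3 (−1.67) and DDIT3 (−1.31) were among them. Quantile normalization ended the heat shock call (adjusted p = 0.124), and the ATF4 call ended without HES-1 LN replicate 2 (adjusted p = 0.0519) and without HES-1 (adjusted p = 0.0501).

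State markers were not called as lists by camera or by fry. Core pluripotency had 3 of 17 higher and 1 lower, also adjusted over the list alone (median 0.06, adjusted p = 0.316). SOX2 rose by 0.60 ± 0.08, PRDM14 fell by 0.91 ± 0.19 and NANOG was at −0.24 ± 0.15 (adjusted p = 0.305). Formative markers had 4 of 16 higher and 1 lower, 4 and 2 adjusted over the list alone (median 0.07, adjusted p = 0.392). OTX2, an epiblast transcription factor, fell from 7807 to 5391 (−0.57 ± 0.17, adjusted p = 0.0295), whereas ZIC2 was at −0.59 ± 0.28 (adjusted p = 0.168). The OTX2 call ended (adjusted p = 0.0503 to 0.0731) when either H7 conventional library, either H7 LN library, HES-1 LN replicate 1 or HES-2 conventional replicate 0 was left out, and without line H7 (adjusted p = 0.301). Primed markers had 5 of 25 higher and 3 lower on both counts (median 0.08, adjusted p = 0.809), with SFRP2 at 0.86 and CDH2 at −1.25. Naive markers had 5 of 28 higher and 3 lower, 6 and 5 adjusted over the list alone (median 0.24, adjusted p = 0.403). Of these TBX3 fell by 2.54 and CPT1A fell by 2.31, and KLF17 had means of 2.65 and 6.12 (0.44 ± 0.55, adjusted p = 0.631). HES-2 LN replicate 0 carried low levels of naive genes above those of replicate 1, such as KHDC1L (51.9 against 2.5) and DPPA5 (47.6 against 3.6), and the naive list was not called with or without it.

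Neuroectoderm genes had 3 of 21 lower on both counts (median −0.78, adjusted p = 0.0874), among them PAX6 (−2.88). That list passed downward (adjusted p = 0.0218 to 0.0486) when any library of conventional HES-1, conventional HES-2 or LN HES-2 was left out, and it turned to a median of 0.41 and an upward call without the H7 LN libraries (adjusted p = 0.0461). FGF and ERK targets had 1 of 19 higher and 5 lower, 1 and 6 adjusted over the list alone (median −0.23, adjusted p = 0.0871). They passed downward without HES-1 naive replicate 1 (adjusted p = 0.0323) or HES-2 LN replicate 0 (adjusted p = 0.0461), and under quantile normalization (adjusted p = 0.0263).

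Matrix genes went both ways. Of 33 basement membrane and integrin genes 3 rose and 12 fell, 5 and 12 adjusted over the list alone (median 0.01 but mean −0.19, camera downward, adjusted p = 0.134). The type IV collagen gene COL4A6 fell by 1.24 and NID1, for nidogen, rose by 0.70. Of 23 fibroblast genes, markers of the feeder cell type, 3 rose and 7 fell, 5 and 8 adjusted over the list alone (median −0.52, adjusted p = 0.313). FN1, for fibronectin, fell from 35305 to 4135 (−3.03 ± 0.51), whereas COL1A1, for type I collagen, rose from 2667 to 9394 (1.65 ± 0.28). The fibroblast list passed downward without line H7 (median −0.59, adjusted p = 0.0398). The basement membrane list did so under quantile normalization (adjusted p = 0.0406), without genes of the long arm of chromosome 1 (adjusted p = 0.0306) and without the H7 LN libraries (adjusted p = 0.0492).

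The remaining lists were not called by camera. Fry called 18 lists, namely the 17 that camera called and the basement membrane list downward (adjusted p = 2.83e-04). Amnion and trophoblast genes had 1 of 20 higher and 3 lower on both counts (median −0.26, adjusted p = 0.433). DNA methylation genes had 1 of 14 higher and 0 lower, and 0 in either direction adjusted over the list alone (median −0.12, adjusted p = 0.523). Imprinted genes had 1 of 22 higher and 4 lower, 4 and 5 adjusted over the list alone (median 0.004 and mean 0.03, camera downward, adjusted p = 0.793). Class I antigen presentation had 1 of 9 higher and 0 lower on both counts (median −0.12, mean 0.07, camera upward, adjusted p = 0.745). Rescaling each library to the same total left 34.3% of the calls on the higher side, against 49.1% as deposited. Leaving out H7 lowered the higher calls to 1040, and a model on the 8 group means called 5 higher and 64 lower.

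**Figure D2:**
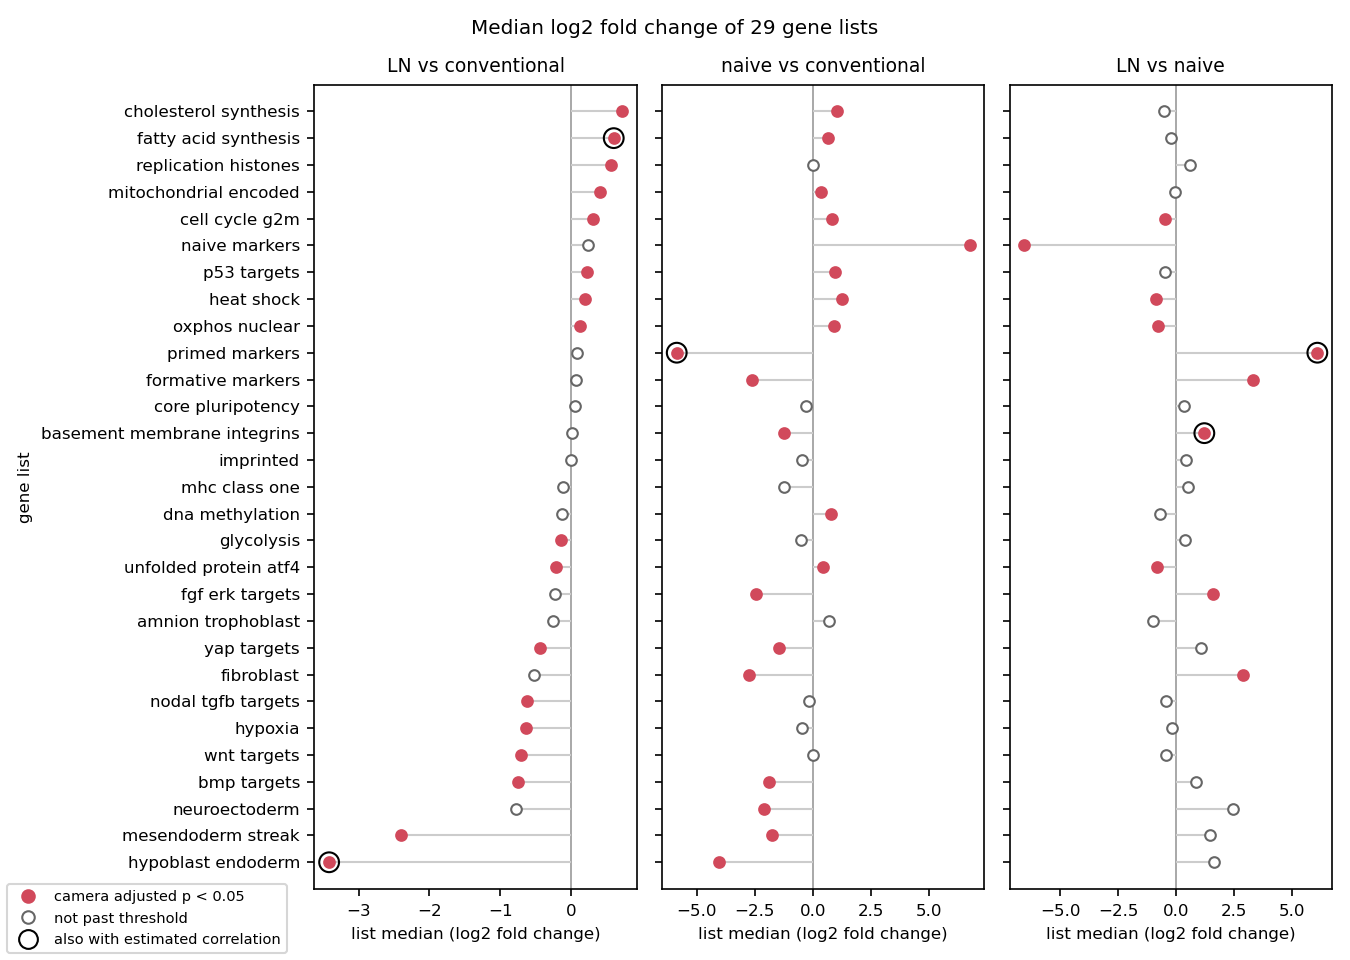
Median log2 fold change of each of the 29 gene lists in the 3 culture comparisons; filled points passed camera at adjusted p below 0.05 and ringed points also passed with an estimated correlation. The hypoblast and endoderm list lies at −3.42 in LN against conventional cells, and the primed markers at −5.87 in naive against conventional cells.

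The difference between LN and conventional cells, here called the LN effect, was also measured in each line, and it differed between lines. In H7 it joins the culture with a difference along the long arm of chromosome 1, given below, and these data cannot separate them. LN cells of H7 had 2727 genes higher and 2560 lower than conventional H7 cells, HES-1 had 583 and 819, and HES-2 had 981 and 1348. Called in all 3 lines were 146 genes upward and 245 downward, where independent lists would share 3.63 and 6.57. HES-1 and HES-2 shared 295 higher and 531 lower genes (27.6 and 53.2 if independent). H7 shared 291 and 338 with HES-1 (76.7 and 101.1 if independent) and 381 and 429 with HES-2 (129.0 and 166.4). Calls also went opposite ways. Of the genes higher in H7, 63 were lower in HES-1 and 185 in HES-2. Of those lower in H7, 43 were higher in HES-1 and 79 in HES-2. Of those higher in HES-1, 18 were lower in HES-2, and 0 went the other way. The LN effect differed between the 3 lines for 2747 genes in an F test. By pairs, 2390 genes differed between HES-1 and H7, 2934 between HES-2 and H7, and 84 between HES-2 and HES-1.

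Among the genes with the smallest F-test p, the collagen gene COL26A1 fell in H7 (−3.45 ± 0.12) and rose in HES-2 (1.12 ± 0.12). The cathepsin gene CTSF rose in H7 (6.82) and fell in HES-1 and HES-2 (−1.07 and −1.25). GDF3, a TGF-beta family ligand of pluripotent cells, rose in H7 (2.88 ± 0.22) and fell in HES-2 (−1.16 ± 0.22). LINC00707 rose in H7 and HES-1 (6.77 and 3.28) and BEX5 in H7 (6.46), whereas ZNF300 fell in H7 (−2.43). The G protein subunit gene GNG7 fell in H7 (−2.40) and rose in HES-1 and HES-2 (0.77 in each). COL6A2 fell in HES-1 and HES-2 (−0.78 and −1.50) and rose in H7 (0.27). LINC02700 rose in H7 and HES-1 (2.40 and 0.62) and fell in HES-2 (−1.13), and SHC1, an adaptor of growth factor receptors on the long arm of chromosome 1, rose in H7 (1.35). DPPA3, a germ cell and naive-state factor, rose in H7 (1.71 ± 0.28) and fell in HES-1 and HES-2 (−1.36 ± 0.26 and −2.54 ± 0.28), with adjusted p = 8.03e-05 for the difference. NANOG rose in H7 (0.32) and fell in HES-2 (−0.90), with adjusted p = 2.91e-04 for the difference.

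The counts within a line fell when any conventional or LN library of that line was left out. In H7, 5287 genes became 3368 or 3393 without conventional replicate 0 or 1 and 3319 without LN replicate 0. In HES-1, 1402 became 619 or 390 without conventional replicate 0 or 1 and 847 without LN replicate 1. In HES-2, 2329 became 865 without conventional replicate 1 and 1122 without LN replicate 0. The difference between lines became 1631 or 1731 without H7 conventional replicate 0 or 1 and 1740 without H7 LN replicate 0. A library left alone in its group was taken to vary like the other groups.

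Genes along the long arm of chromosome 1 were about 2-fold higher in LN than in conventional H7 cells. The median over the 515 protein-coding genes of the arm with a mean of at least 100 was 1.01 (95.3% above 0), against −0.05 over 10669 other autosomal genes, and the LN libraries of H7 each showed it (0.99 and 1.03). All 11 windows of 10 Mb on the arm lay between 0.87 and 1.21, and the other windows of the 274 lay between −0.53 and 0.43. On GRCh38 with GENCODE 29 the arm's tested genes start at position 143736066, after a gap that follows a gene starting at 121519112. The medians of the arm were −0.00 in HES-1 and 0.01 in HES-2. The arm held 517 of the 2727 genes called higher in H7 (18.96%, against 4.33% of tested genes), and 4752 genes outside the arm were called in H7. Among the genes named above as higher in LN than in conventional cells, CENPF, NID1, HMCN1 and PHLDA3 lie on the arm. Their changes over all lines therefore include this H7 difference, though each was also higher in LN cells of HES-1 and HES-2. Genes named above as lower, such as LEFTY2, lie on the arm too, and there the H7 difference of the arm runs against the fall. Without genes of the arm, 1650 genes were higher in LN than in conventional cells over all lines, against 1823 with them.

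**Figure D3:**
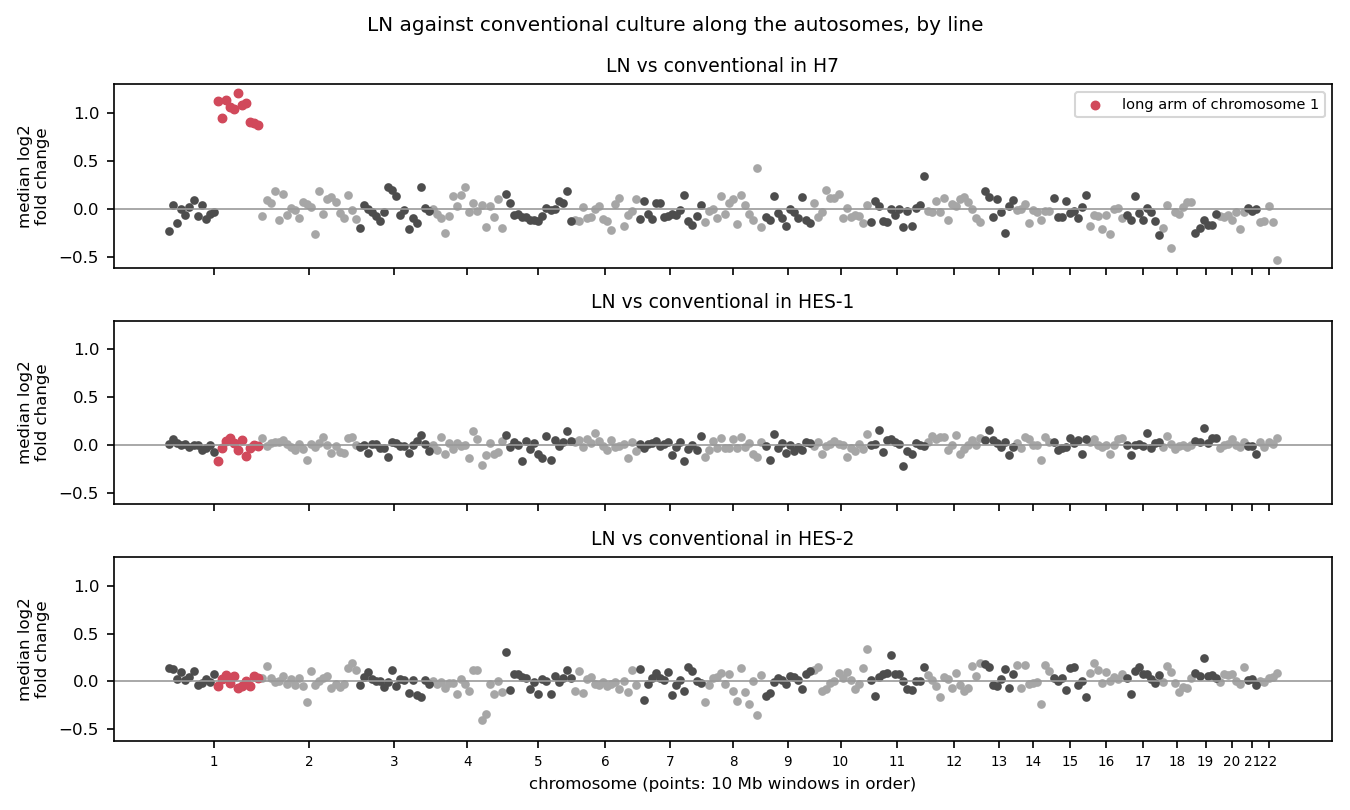
Median log2 fold change of LN against conventional cells in 10 Mb windows along the autosomes, in order, for H7, HES-1 and HES-2; each point is a window with at least 10 protein-coding genes. Windows of the long arm of chromosome 1 lie between 0.87 and 1.21 in H7, and all other windows of H7 lie at or below 0.43.

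Naive cells differed from conventional cells across most of the transcriptome, with pre-implantation genes switched on and primed and lineage genes nearly silent. The naive factor KLF17 went from a mean of 2.65 to 2425 ± 719.9 (SD, n = 4), a log2 change of 9.81 ± 0.67 (SE). ZIC2, a primed-state factor, went from 6866 to 11.4 (−9.27 ± 0.34). Naive libraries had 6747 genes higher and 7459 lower than conventional ones, 3617 and 5505 of them by at least 2-fold. Of 28 naive markers 26 rose, 1 fell and 1 did not pass (median 6.76, adjusted p = 2.47e-11, and adjusted p = 0.0828 with an estimated correlation). Of 25 primed markers 24 fell, 0 rose and 1 did not pass (median −5.87, adjusted p = 8.03e-12, and adjusted p = 0.0124 with an estimated correlation). With an estimated correlation the primed list alone passed. Adjusted over the list alone, every count of this comparison was the same except that of the histones.

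Among the largest increases were ZNF729 (11.67), KHDC1L (11.66), KHDC3L (11.45), a maternal-effect gene of oocytes and early embryos, TRIM60 (10.47), DPPA5 (10.40), FAM151A (10.25) and LINC02864 (10.15). The imprinted noncoding RNAs MEG3 (10.16) and MEG9 (10.14) rose as well. MEG3 stood at 34.3 and 42.2 in conventional HES-1 and HES-2 cells, 31810 and 44250 in naive ones, and 10810 in conventional H7 cells. Among the largest decreases were IGFBP5 (−10.23), CER1 (−10.06), STC1 (−9.99), CST1 (−9.71) and CYP26A1 (−9.51), which degrades retinoic acid. ADAMTS19 (−9.40), HEPH (−9.14), FEZF1 (−9.03), a forebrain factor, and JAKMIP2-AS1 (−8.92), an antisense transcript, followed. DPPA3 rose by 5.44, NANOG rose by 2.46 and POU5F1 rose by 0.42, while SOX2 fell by 0.33 and OTX2 fell by 4.44. The POU5F1 call ended under quantile normalization (−0.0855, adjusted p = 0.535), after rescaling to the same total (adjusted p = 0.677) and without HES-2 (adjusted p = 0.0713).

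Formative markers fell in 14 of 16 cases and 2 rose (median −2.61, adjusted p = 1.69e-04, and adjusted p = 0.0750 with an estimated correlation), with SOX11 at −7.49 and LIN28B at 1.81. FGF and ERK targets fell in 16 of 19 and 2 rose (median −2.47, adjusted p = 7.93e-04, and adjusted p = 0.446 with an estimated correlation), among them the ERK phosphatase gene DUSP6 (−7.49) and ETV1 (−5.58). Hypoblast and endoderm genes fell in 18 of 20 (median −4.07, adjusted p = 1.61e-05, and adjusted p = 0.227 with an estimated correlation). Fibroblast genes fell in 17 of 23 and 2 rose (median −2.75, adjusted p = 5.28e-04, and adjusted p = 0.241 with an estimated correlation). The surface gene THY1 was at −7.63, COL1A1 at −2.44 and TWIST1 at 3.46. Basement membrane and integrin genes fell in 21 of 33 and 6 rose (median −1.24, adjusted p = 0.00456, and adjusted p = 0.0559 with an estimated correlation), with COL4A6 at −7.10. YAP targets fell in 17 of 20 and 3 rose (median −1.47, adjusted p = 0.00354, and adjusted p = 0.241 with an estimated correlation), with AXL, a receptor kinase, at −5.67.

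BMP targets fell in 10 of 14 and 1 rose (median −1.88, adjusted p = 0.0149, and adjusted p = 0.510 with an estimated correlation). Streak and mesendoderm genes fell in 13 of 19 and 2 rose (median −1.75, adjusted p = 0.0134, and adjusted p = 0.367 with an estimated correlation). Neuroectoderm genes fell in 12 of 21 and 1 rose (median −2.13, adjusted p = 0.0245, and adjusted p = 0.569 with an estimated correlation).

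Respiratory genes rose in 35 of 39 cases and 1 fell (median 0.89, adjusted p = 9.40e-11, and adjusted p = 0.117 with an estimated correlation), among them UQCRH (2.09) and COX7B (2.04). Genes of G2 and mitosis rose in 19 of 22 and 1 fell (median 0.81, adjusted p = 1.37e-05, and adjusted p = 0.241 with an estimated correlation). Heat shock genes rose in 11 of 13 (median 1.26, adjusted p = 2.40e-04, and adjusted p = 0.241 with an estimated correlation), with the chaperone gene DNAJB1 at 2.24. Cholesterol synthesis genes rose in 19 of 26 and 3 fell (median 1.04, adjusted p = 7.34e-04, and adjusted p = 0.510 with an estimated correlation), with MSMO1 at 2.48. Fatty acid synthesis genes rose in 11 of 15 and 2 fell (median 0.63, adjusted p = 0.0284, and adjusted p = 0.367 with an estimated correlation). ATF4 and unfolded protein genes rose in 13 of 22 and 3 fell (median 0.42, adjusted p = 0.0149, and adjusted p = 0.446 with an estimated correlation), with TRIB3 at 3.55. p53 targets rose in 14 of 19 and 4 fell (median 0.97, adjusted p = 0.0313, and adjusted p = 0.446 with an estimated correlation). Mitochondrially encoded genes rose in 10 of 13 (median 0.37, adjusted p = 0.0235, and adjusted p = 0.556 with an estimated correlation).

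DNA methylation genes rose in 10 of 14 and 4 fell (median 0.80, adjusted p = 0.0459, and adjusted p = 0.297 with an estimated correlation). DNMT3L, a cofactor of DNA methylation, rose by 8.36, while the methyltransferase gene DNMT3B fell by 2.13. The call of this list ended without HES-1 naive replicate 0 or 1 (adjusted p = 0.0552 and 0.0522), with no line term (adjusted p = 0.0669), with a replicate block (adjusted p = 0.0537) and with a filter at 50 (adjusted p = 0.0893). That filter also ended the calls of fatty acid synthesis (adjusted p = 0.0622) and p53 targets (adjusted p = 0.0699). Not called by camera were core pluripotency (7 higher and 9 lower of 17, median −0.31 but mean 0.02, camera downward) and imprinted genes (7 and 9 of 22, median −0.46 but mean 0.70, camera downward). Hypoxia (2 and 10 of 20, median −0.45), Nodal and TGF-beta (6 and 7 of 18, median −0.15) and WNT genes (6 and 7 of 19, median −0.02) were not called by it. Nor were amnion and trophoblast (7 and 5 of 20, median 0.69), class I presentation (2 and 4 of 9, median −1.24) and replication histones (3 and 3 of 19, median 0.02). The histone counts were 1 and 2 adjusted over the list alone. Fry, which does not compare a list with other genes, called 27 of the 29 lists, all but the imprinted (adjusted p = 0.0847) and histone lists (adjusted p = 0.925). Its calls were downward for core pluripotency (1.07e-05), hypoxia (7.52e-06), Nodal (0.00130), WNT (2.12e-05), class I presentation (0.00108) and glycolysis (1.07e-06), and upward for amnion and trophoblast (0.00130). Glycolysis (4 and 12 of 21, median −0.51, adjusted p = 0.0652) passed downward without HES-1 conventional replicate 1 (adjusted p = 0.0493) or HES-2 naive replicate 1 (adjusted p = 0.0443).

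Within HES-1 the naive effect comprised 6097 higher and 6674 lower genes, and within HES-2 5981 and 6579. It differed between the lines for 555 genes, and for 297 or 266 without HES-1 conventional replicate 0 or 1 and 322 or 331 without HES-2 conventional replicate 0 or 1. Quantile normalization ended the calls of fatty acid synthesis and DNA methylation (adjusted p = 0.308 for each), mitochondrially encoded (adjusted p = 0.630), p53 (adjusted p = 0.117), ATF4 (adjusted p = 0.579) and neuroectoderm genes (adjusted p = 0.0713). It gave downward calls to core pluripotency (median −0.83, adjusted p = 0.0387), hypoxia (median −0.93, adjusted p = 0.0378) and glycolysis (median −0.96, adjusted p = 4.17e-04). Rescaling to the same total ended those of streak (adjusted p = 0.0536), mitochondrially encoded (adjusted p = 0.161) and neuroectoderm genes (adjusted p = 0.126), and called glycolysis downward (adjusted p = 0.0394). That rescaling moved the median of all genes from −0.07 to −0.43 and the higher share of the calls from 47.5% to 32.1%.

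**Figure D4:**
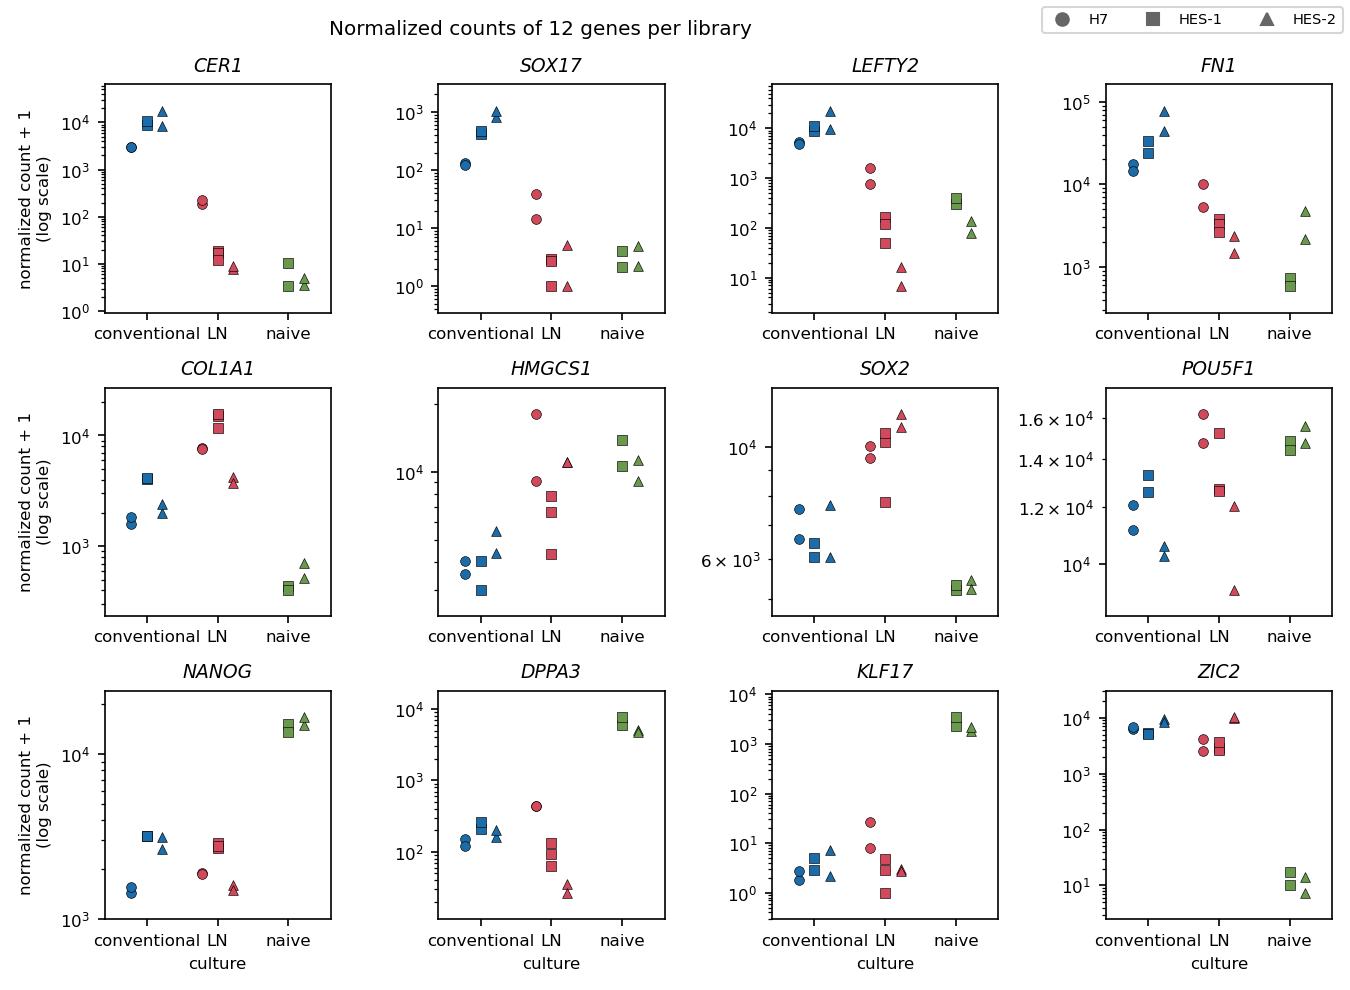
Normalized counts plus 1 of 12 genes in each of the 17 libraries, on a log axis, by culture, with symbols for lines. CER1, SOX17, LEFTY2 and FN1 lie lower in LN than in conventional libraries of the same line, COL1A1 higher, and KLF17 is high in the naive libraries (mean 2425).

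LN cells carried more RNA of primed, formative and matrix genes than naive cells and far less of naive genes. With an estimated correlation the primed and basement membrane lists passed, and formative (adjusted p = 0.0623) and naive markers (adjusted p = 0.0798) did not. LN libraries had 7383 genes higher and 6785 lower than naive ones, 5306 and 3612 of them by at least 2-fold. Primed markers were higher in 24 of 25 cases and lower in 0 (median 6.08, adjusted p = 2.06e-12, and adjusted p = 0.0101 with an estimated correlation), led by the WNT antagonist gene SFRP2 (9.39) and PTPRZ1 (9.28). Naive markers were lower in 26 of 28 and higher in 1 (median −6.56, adjusted p = 1.77e-11, and adjusted p = 0.0798 with an estimated correlation), led by ZNF729 (−10.80) and TRIM60 (−10.72). KLF17 was at −9.37, DPPA3 at −6.20 and NANOG at −2.70, while SOX2 was at 0.92, OTX2 at 3.87 and ZIC2 at 8.68. COL1A1, with a mean of 516.2 ± 133.03 (SD, n = 4) in naive cells, was higher in LN cells (4.09).

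Basement membrane and integrin genes were higher in 22 of 33 cases and lower in 6, and 23 were higher adjusted over the list alone (median 1.21, adjusted p = 0.00395, and adjusted p = 0.0423 with an estimated correlation). COL4A6 was at 5.86 and the perlecan gene HSPG2 at 4.21. Formative markers were higher in 13 of 16 and lower in 2 (median 3.33, adjusted p = 1.43e-04, and adjusted p = 0.0623 with an estimated correlation). FGF and ERK targets were higher in 14 of 19 and lower in 3 (median 1.58, adjusted p = 0.00718, and adjusted p = 0.751 with an estimated correlation), with DUSP6 at 7.57. Fibroblast genes were higher in 15 of 23 and lower in 3 (median 2.87, adjusted p = 0.00379, and adjusted p = 0.401 with an estimated correlation), with THY1 at 8.27.

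Respiratory genes were lower in LN cells in 33 of 39 cases and higher in 1 (median −0.78, adjusted p = 2.46e-09, and adjusted p = 0.166 with an estimated correlation). ATF4 and unfolded protein genes were lower in 16 of 22 and higher in 1, or 2 adjusted over the list alone (median −0.85, adjusted p = 0.00145, and adjusted p = 0.401 with an estimated correlation). Genes of G2 and mitosis were lower in 14 of 22 and higher in 2 (median −0.47, adjusted p = 0.00395, and adjusted p = 0.605 with an estimated correlation). Heat shock genes were lower in 11 of 13 and higher in 1 (median −0.87, adjusted p = 0.00379, and adjusted p = 0.401 with an estimated correlation). The other counts of the 10 called lists were the same adjusted over the list alone. The remaining 19 lists were not called by camera, though YAP targets (median 1.05, adjusted p = 0.0890) passed upward without HES-1 naive replicate 1 (adjusted p = 0.0220). Fry called 23 of the 29 lists, among them YAP targets (2.07e-06), core pluripotency (1.88e-06), glycolysis (1.96e-05) and hypoblast genes (6.20e-05) upward. Signs differed for WNT targets (median −0.43, mean 0.13, camera downward, fry upward), hypoxia (median −0.19, mean 0.20, camera upward) and imprinted genes (median 0.41, mean −0.67, camera upward). Quantile normalization ended the ATF4 (adjusted p = 0.110), G2 (adjusted p = 0.794) and heat shock calls (adjusted p = 0.0823), and the FGF call ended without HES-2 (adjusted p = 0.0616). Glycolysis was called upward under quantile normalization (adjusted p = 0.0348), and rescaling to the same total called DNA methylation genes downward (adjusted p = 0.0408). Rescaling to the same total moved the higher share of the calls from 52.1% to 65.04% and the median of all genes from 0.06 to 0.35.

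Further large increases in LN over naive cells were KLHL4 (9.46), JAKMIP2-AS1 (9.23), the fibrillar collagen gene COL11A1 (9.10), KLHDC7A (9.02) and ADAMTS19 (8.82). The cation channel gene TRPC4 (8.82) and TNIK (8.66), a kinase of WNT signalling, followed. Further decreases were KHDC1L (−10.69), ZNF736 (−10.15), MEG3 (−10.10), LINC02864 (−10.08), KHDC3L (−9.93), FAM151A (−9.63), DNMT3L (−9.59) and OLAH (−9.54). The MEG3 decrease was seen in HES-1 and HES-2, the lines with naive cells. H7 enters the value only through its LN and conventional libraries, and its LN libraries stood at 19256 and 20661.

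Of all tested genes, 864 were higher and 780 lower in LN cells than in both other cultures. Independent lists would share 649 and 619, and libraries simulated with no effect gave 0 and 0, which says nothing on the overlap of real effects. With LN replicates split between the comparisons, the counts were 258 and 373 in a first split (180.4 and 246.8 if independent) and 354 and 432 in the other (251.4 and 303.7 if independent). NODAL, the ligand, was lower than in both, with means of 1456 in conventional, 268.2 in LN and 4213 in naive cells (−3.43 ± 0.71 and −5.43 ± 0.83). The fall came from HES-1 (−3.19 ± 0.44) and HES-2 (−6.83 ± 0.48). In H7, which has no naive cells, NODAL was not called (−0.40 ± 0.48, adjusted p = 0.602), and the LN effect differed between lines (adjusted p = 2.93e-04). The endoderm factors GATA6 (−2.67) and HNF4A (−4.19) were lower than in naive cells, but they were 2 of only 4 such members of the hypoblast list. Against naive cells 11 of its 20 genes were higher (median 1.63), and the list was called upward by fry (adjusted p = 6.20e-05) but not by camera (adjusted p = 0.217). PPP1R17 was higher than in both, with means of 760.02 in LN, 91.3 in conventional and 20.8 in naive cells. Without H7 the higher count fell to 566.

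Where LN cells lie along the axis from conventional to naive cells was measured between lines that share no library. The slope of the LN effect on the naive effect over 20740 genes was 0.08 for H7, 0.06 for HES-1 and 0.05 for HES-2. The correlation across genes, which are not independent replicates, was r = 0.154, 0.161 and 0.115 (Spearman's rho 0.148, 0.0718 and 0.0522). Of the genes lower in LN cells of HES-1, 53.4% were lower and 25.9% higher in naive cells of HES-2, against 31.7% and 28.8% of all tested genes. Of those higher in LN cells of HES-1, 36.5% were lower and 39.97% higher.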

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

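The tests of differences between lines were set beforehand, and the tests on the long arm of chromosome 1, its count included, were chosen after the result was seen. Groups of a line and a culture held 2 or 3 libraries, and no test for outlying libraries was applied to them.

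Effects that differed between lines met the criterion for a closer look. For H7 they cannot be told apart from changes tied to the difference along the long arm of chromosome 1, on or off the arm. The LN effect differed between the 3 lines for 2747 genes, with 2390 genes between HES-1 and H7, 2934 between HES-2 and H7, and 84 between HES-2 and HES-1. The naive effect differed between HES-1 and HES-2 for 555 genes. Of the 88 genes named for LN against conventional cells 37 differed between lines in the LN effect, and of the 112 named for naive against conventional cells 6 differed in the naive effect. DPPA3 and NANOG were higher in LN cells of H7 (1.71 ± 0.28 and 0.32 ± 0.10) and lower in LN cells of HES-2 (−2.54 ± 0.28 and −0.90 ± 0.10), with adjusted p = 8.03e-05 and 2.91e-04 for the difference. In HES-1, DPPA3 fell by 1.36 ± 0.26, and NANOG was at −0.20 ± 0.09 (adjusted p = 0.224).

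Of the 898 tested genes on the long arm of chromosome 1, 418 differed between lines in the LN effect. After a trend on GC content and gene length was removed, the median of the arm in H7 stayed at 1.03 above other autosomal genes (1.06 before), with an SD over genes of 0.724, which argues against such a bias as the whole cause. Libraries of HES-1 or HES-2 under an H7 label are also argued against. Of the 36 genes that tell H7 from both other lines in conventional culture, 25 (69.4%) lay closest to H7 in the H7 LN libraries. In LN libraries of HES-1, 2.78% lay closer to H7 than to HES-1, with HES-2 not compared. The genes were picked for a gap between these lines in conventional culture, so that low value is no separate support. No such value was computed for LN libraries of HES-2. All 11 windows of the arm lay above every window elsewhere, which is what the arm was picked for and is no further test. A gain of the arm in the H7 cells kept on laminin is a candidate explanation, and copies of the arm were not measured. A library from cells outside the study was not excluded, and an effect of LN culture on the arm in H7 alone, with no such effect in HES-1 and HES-2, was not tested separately.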

How the results depend on the processing

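The settings without genes of the long arm of chromosome 1, without the H7 LN libraries and, for genes apart from both cultures, without line H7 were chosen after the data were seen; the others were set beforehand. For counts and values that answer a comparison, 519 of 552 recomputed values stayed within 1.5 times the count or within the spread between replicates, and 33 moved. For gene lists 2920 of 3042 kept direction and call, 78 lost the call, 43 gained it and 1 reversed. For named genes 10439 of 10915 kept both, 460 lost the call, 9 gained it and 7 reversed. Pseudocounts of 0.5 and 5 changed no call of a list or a named gene.

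With an estimated correlation camera called 2 lists in LN against conventional cells, 1 in naive against conventional cells and 2 in LN against naive cells, against 17, 20 and 10 with the preset one, and the cause was not tested.

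The genes higher in LN than in conventional cells numbered 1823 and became 1182 with no line term, 1040 without H7, 1171 without HES-1 (1179 lower, against 1893) and 1178 without the H7 LN libraries. On the 8 mean profiles they were 5, with 64 lower, where each line and culture counted once. Cell means averaged over lines gave 3024 higher and 2938 lower. With a replicate block 1150 were higher; the differences between replicates 0 and 1 correlated at −0.05 to 0.04 between cultures of a line, so the numbers do not pair the libraries, and the block costs calls without showing a weaker effect. Genes higher in LN than in both cultures were 864 and became 566 without H7. Settings that leave out a line or average libraries have fewer values to test, and the cause of the other moves was not tested.

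Leaving out 1 library at a time gave 3319 to 5446 genes for LN against conventional cells in H7 (5287 with all), 390 to 1505 in HES-1 (1402) and 865 to 2486 in HES-2 (2329). It gave 1631 to 2911 for the difference between lines (2747) and 266 to 664 for the naive difference (555). The lowest counts came without H7 LN replicate 0, HES-1 conventional replicate 1, HES-2 conventional replicate 1, H7 conventional replicate 0 and HES-1 conventional replicate 1, in that order, and a lone library was assumed to vary like the other groups.

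The distance from conventional to LN cells as a share of that from conventional to naive cells was 0.343 in HES-1 and 0.388 in HES-2. It moved to 0.373 and 0.435 over all tested genes and to 0.309 and 0.354 with a pseudocount of 5.

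Reversals among results called in the main test or in the alternative were few, and the cause was not tested. When each library was rescaled to the same total, POU5F1 in LN against naive cells went from −0.26 to 0.0418. Quantile normalization took it to 0.15, POU5F1 in naive against conventional cells to −0.0855, DNMT3A to −0.11 in naive against conventional and 0.0447 in LN against naive cells, and the histone gene H2BC9 to 0.00132 in naive against conventional cells. Without HES-1, FOS in LN against naive cells went to 0.0781. Without the H7 LN libraries the neuroectoderm median in LN against conventional cells went from −0.78 to 0.41. Read counts were not given, so the limit that depth sets on genes near 0 could not be computed.

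Further list calls changed under settings not given above, and the cause was not tested. In LN against conventional cells, neuroectoderm passed downward with no filter (adjusted p = 0.0373), with cell means averaged over lines (0.0260), without HES-1 (0.0131) and without HES-2 (0.00109), FGF and ERK targets passed downward with only the libraries of the 2 cultures (0.0121), without H7 (0.0356) and without the H7 LN libraries (0.0327), and the ATF4 call ended with a replicate block (0.0531). In naive against conventional cells, glycolysis passed downward with no filter (0.0385), DNA methylation and fatty acid synthesis lost the call without HES-1 (0.0858 and 0.0584), and p53 and ATF4 genes lost it without HES-2 (0.0570 for each). In LN against naive cells, neuroectoderm passed upward with cell means (0.00504), with only the 2 cultures (0.00879) and without H7 (0.00841), and BMP targets did so with cell means (0.0435) and without H7 (0.0407). YAP targets passed upward with no filter (0.0419) and without HES-1 (0.0179), DNA methylation downward with no filter (0.0243) and without HES-2 (0.0451), and cholesterol synthesis downward without HES-2 (0.0474).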

Other observations

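Tests on other groupings of the libraries were set beforehand, and the tests on endoderm, on the HLA region, on metallothioneins, on naive genes in single libraries and on the chromosome 19 window were chosen after the result was seen.

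Other groupings of the same libraries were tried to see how many genes they call. The model was fitted to those libraries alone, so the real counts differ from the 3716, 14206 and 14168 genes called over all 17 libraries. For LN against conventional cells, 1 of 100 groupings of the 13 libraries (of 1716 possible), the real one, gave as many genes as the real 4093, and the highest other gave 5. For naive against conventional cells, 1 of the 35 groupings of the 8 libraries did so (13876 genes, highest other 19). For LN against naive cells, 1 of 100 groupings of the 9 libraries (of 126 possible) did so, with 13712 genes. The real grouping called the most genes in each case. Being 1 of 35 or 1 of 100 groupings, it argues against chance only if libraries count as separate units, which the labels do not state. Libraries were moved across lines as well as within them, and a wrong grouping puts the culture difference into the spread, which lowers its calls. With each line and culture counted once, LN against conventional cells gave 5 genes higher and 64 lower. The highest other grouping of the last comparison gave 8411 genes, which points to a structure of the libraries that other groupings share in part.

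The lower RNA of hypoblast and endoderm genes in LN cells has 3 candidate explanations. Loss of feeder fibroblast RNA could not be decided by the 23 fibroblast genes (2 of them in other lists). Their median was −0.52 (SD 1.35 over genes), 2.90 above the hypoblast median of −3.42. COL1A1 rose from 2667 to 9394 while FN1 fell from 35305 to 4135. LN cells grew without feeders and still carried COL1A1, so the list does not measure feeder RNA alone. The feeders were mouse cells, and the part that mm10 played is not stated. Lower Nodal signalling and fewer differentiated cells cannot be told apart in bulk RNA. The Nodal list without members of the hypoblast and streak lists was lower in camera (p = 2.83e-04 over 16 genes, median −0.35, 7 lower and 1 higher; p = 0.0726 with an estimated correlation). Of the 20 hypoblast genes, 16 lay below 0 in all 3 lines, which either explanation would give; NODAL itself was not called lower in H7 (−0.40 ± 0.48).

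Some genes of the HLA region on chromosome 6 varied widely between replicates of a group. Between 28 and 34 Mb, 5 of 43 genes with a mean of at least 200 (11.6%) had a within-group SD above 1, namely DAXX, PPP1R10, TUBB, VARS1 and ZBTB12, against 73 of 10732 elsewhere (0.680%, two-sided Fisher's exact p = 1.36e-05). TUBB stood at 289.8 and 10527 in the replicates of LN HES-2, a ratio of 36.3, which is the kind of spread that these genes were picked for and tests no explanation. ZBTB12 is unlike TUBB, with 210.7 to 603.3 in conventional and LN libraries and 0 to 23.9 in naive ones. Reads shared between near-identical copies of genes stay open, because the region was picked for its spread and the transcript reference behind the deposited values is not stated. TUBB itself was called higher in LN than in conventional cells (adjusted p = 0.0408), and that call ended without either H7 conventional library, H7 LN replicate 0, HES-1 conventional replicate 0, any HES-1 LN library, either HES-2 conventional library or HES-2 LN replicate 0 (adjusted p = 0.0518 to 0.0972, and 0.0105 to 0.254 over all settings).

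Metallothionein genes were lower in LN cells than in both other cultures, in 8 of 8 members as deposited and under both other scalings. Their median was −3.01 against conventional and −4.90 against naive cells. Against conventional cells, 7 of the 8 were higher in naive cells as deposited and 5 under each other scaling. MT2A had means of 2071 in conventional, 363.5 in LN and 4151 in naive cells. Members of this family are near-identical, so the values of single genes are uncertain.

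A window on chromosome 19 from 20 to 30 Mb was picked for the largest excess of the naive effect in HES-2 over HES-1. It held 34 protein-coding genes with a mean of at least 100 over all libraries, 29 of them with zinc finger symbols. In naive against conventional cells 28 were higher and 1 lower, and the median change was 0.94 in HES-1 and 2.90 in HES-2. Genes such as ZNF729, at 0 to 19.97 outside naive cells, met the limit through their naive values, which raises the count of 28. The difference of 1.96 compares with 0.482 in the next highest of 274 windows, a rank that follows from the choice. For 11 genes the naive effect differed between the lines, and all 11 were higher in HES-2, the direction the window was picked for. Among them were ZNF626 (0.75 against 8.12, adjusted p = 3.06e-07) and ZNF486 (3.12 against 9.70). Genes of this cluster are near-identical, which leaves the share of single genes uncertain.

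Low levels of naive genes differed between libraries of other cultures. Over the 10 genes with the largest increase in naive cells, the median level as a percent of the naive mean was 0.294% in HES-2 LN replicate 0 and 0.0370% in replicate 1. It was 0.423% and 0.233% in the LN libraries of H7, 0.0295 to 0.0799% in those of HES-1 and 0.0390 to 0.105% in the conventional libraries.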
